A study of Mus musculus with 6 samples.

How the data were processed

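RNA was extracted from sorted Six2-expressing progenitors of E16.5 mouse kidneys, from 3 control and 3 mutant pools of 4 embryos each, and sequenced with paired reads of 100 bases on 2 lanes, per the labels' protocols, which also state an RNA integrity number above 9, amplification with the Ovation RNA-Seq System V2 and about 70 M reads per sample. The genome build was mm10, and FastQC and limma are named, per the submitters' processing notes; column names carry the word subread, the name of an aligner, per the file headers. The authors deposited 1 table of RPKM values for 27179 Entrez Gene entries in the 6 libraries, normalized for gene length and for library depth. The strand setting, the counting tool and the annotation are not given in the sources used here, so reads of overlapping and antisense genes may be mixed. Gene symbols were matched for 25293 of the 27179 entries. Positions came from an annotation of the same build, and 497 of the tested genes had none.

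RPKM values of genes with few reads fall on a grid of whole reads, so depth, gene length and whole reads were worked out from the table. Reads were taken as whole within 0.1 of a read, and they were recovered for all 13463 tested genes; their sums came to between 100.03% and 100.22% of the depth. On simulated data the recovery gave the right reads for 98.92% of 3797 genes. The depths lie well below the reads stated per sample, and whether a unit was a read or a read pair is not known, so "reads" stands for either. At these depths 1 read on a gene of 1 kb is worth between 0.0277 and 0.0362 RPKM. Intervals on read ratios are exact 95% binomial intervals and floors are 3 reads; both cover counting error only, since amplified reads are not independent molecules.

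Genotypes were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), for genes with a mean of at least 0.5 RPKM over the 6 libraries, with 1 term for genotype, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. The test, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were the targeted locus, the 10 largest log2 fold changes in each direction past the threshold with a mean of at least 1 RPKM and groups that did not overlap, up to 4 genes of lowest p in each of 22 gene lists, and Cftr, Six2, Cited1, Wnt4, Bcl2l11, Cdkn1a and Mki67; predicted genes without an approved symbol were passed over, and some genes that the rule names are not reported here. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Seed sites were counted in the longest annotated 3' UTR of each gene, against other tested genes with a 3' UTR, and set against shuffled 8mers of the same composition and 10000 random lists matched on UTR length and expression; sites and shared sequence were counted with Python 3.11.15. Sequence sharing was measured as the percent of a gene's 31-base words found in a non-overlapping gene, for 94.01% of tested genes. The minimum of 20% was set after results had been seen, and genes below it are named as without shared sequence.

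The fit was tested on simulated data for this comparison, with 13308 genes passing the filter. It called 44.8% of genes changed 1.5-fold, 90.5% of those changed 2-fold and 100% of those changed 4-fold, and 5.66% of its calls were false. In 20 simulated tables with no change, 1 table had any call when gene variances were drawn from the prior that limma estimates, and 9 tables had calls, at most 4 genes in a table, when variances were drawn from those of the data; p-values of a few highly variable genes may therefore be too small. Camera called 10 of 10 shifted lists and 0 of 30 others. Simulated genes were drawn independently of each other, so this could not test the preset correlation on lists whose members vary together. The estimated correlation was 0.66 in the interstitium list and 0.42 in the macrophage and leukocyte list. Alternatives were the pseudocount, the filter, scaling, variance model, sample weights, a replicate block, leaving out each library, the threshold and the kind of seed site; voom on recovered reads, depth without mitochondrial ribosomal RNA, a covariate for Y-linked expression, robust variance moderation and a restriction to genes off chromosome 14 without shared sequence were added after the data were seen.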

Results

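Whole-transcriptome RNA was measured in nephron progenitors, the cells that give rise to the nephrons of the kidney, sorted from E16.5 mouse kidneys by a green fluorescent reporter under control of Six2. Control progenitors carried the Six2TGC transgene, which drives Cre recombinase in these cells, and mutant progenitors carried in addition floxed copies of the miR-17~92 microRNA cluster. Each genotype had 3 libraries, and each library was a pool from 4 embryos. Library depth, worked out from the deposited RPKM values, was 29477464, 36134381 and 28117790 reads in control replicates 1, 2 and 3 and 30264067, 27785397 and 27602025 reads in mutant replicates 1, 2 and 3. The comparison asks which transcripts differ between nephron progenitors with and without removal of the cluster. The control labels name no floxed copies, and the labels give no strain background. A difference on any chromosome may therefore come from the deletion or from genetic background carried with the floxed copies. The design cannot tell these apart.

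The targeted locus was measured first, as reads of whole-transcriptome RNA counted to each annotated entry. Levels of the mature, processed microRNAs were not measured. Mir17 (Entrez Gene 723905), the first microRNA of the cluster, at chromosome 14, 115043671 to 115043754 (mm10), fell from 9.29 ± 2.94 RPKM in controls to 0.262 ± 0.454 in mutants (SD, n = 3 each; limma adjusted p 8.54e-05). It had 31, 26 and 16 reads in the control libraries and 2, 0 and 0 in the mutant libraries, a ratio of read rates of 0.03 (95% counting interval 0.00356 to 0.112). Mir18 had 16 reads over the controls and 0 over the mutants, at least 4.87-fold lower against a floor of 3 reads over the group (limma adjusted p 0.00347). That floor leaves out the counting error of the control reads, and with it the 95% counting interval of the ratio was 0 to 0.284. Mir20a had 10 and 0 reads, at least 3.05-fold lower on the same floor (95% counting interval of the ratio 0 to 0.488; limma adjusted p 0.00727; 0.0601 without mutant replicate 2, and 0.000483 to 0.0671 over the alternatives run). Mir19a had 5 and 0 reads (0 to 1.19) and Mir19b-1 had 2 and 0 (0 to 5.83), and both of these intervals include no change. Both lay under the expression filter, and exact two-sided permutation tests gave p of 0.1, the smallest that 3 against 3 libraries allow, and 0.4. Mir92-1 was listed at 0 in all 6 libraries, and its position lies inside the Mir17hg entry. In the opposite direction, Mir17hg (Entrez Gene 75957), the host transcript, annotated as a long non-coding RNA at 115044390 to 115046728 on the same chromosome, rose from 44 ± 9.71 to 212 ± 41.1 RPKM (SD, n = 3). Its log2 fold change was 2.26 with a standard error of 0.18 (limma adjusted p 4.93e-05). That entry begins downstream of Mir17, Mir18, Mir19a and Mir20a.

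**Figure D1:**
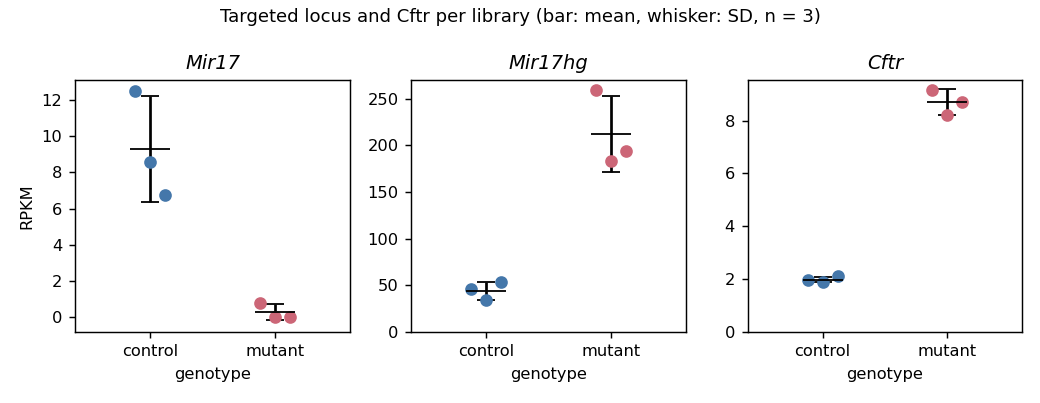
RPKM (vertical axis, linear) of Mir17, Mir17hg and Cftr in each library, by genotype; dots are libraries, bars are means and whiskers are SD over 3 libraries. Mir17 fell to between 0 and 0.787 RPKM in the mutant libraries, while Mir17hg and Cftr rose in each of them.

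Cftr (Entrez Gene 12638; chromosome 6, 18170687 to 18322770), the chloride channel mutated in cystic fibrosis, rose from 1.98 ± 0.112 to 8.7 ± 0.482 RPKM (SD, n = 3), with a log2 fold change of 1.89, a standard error of 0.15 and a limma adjusted p of 3.29e-05. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, rose from 0.326 ± 0.27 to 4.48 ± 3.35 RPKM (SD, n = 3; log2 fold change 2.43, limma adjusted p 0.00561), and its mutant level differed between pools (3.19, 1.96 and 8.28 RPKM). The amino acid transporter gene Slc1a5 rose with a log2 fold change of 1.9. Among genes that fell, Nxph1, a neurexophilin gene, went from 46.9 ± 4.11 to 7.34 ± 4.95 RPKM (SD, n = 3; log2 fold change -2.85, limma adjusted p 0.00264). Ralyl had a log2 fold change of -2.19, Lrrc4c of -2.16 and the fucosyltransferase gene Fut2 of -2.15. The call for Ralyl was lost without mutant replicate 2 (limma adjusted p 0.102), and with no filter on low values or with robust variance moderation neither Ralyl (0.105 and 0.127) nor Nxph1 (0.0629 and 0.0902) passed. With no filter Slc12a1 did not pass either (0.0875).

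Across the transcriptome, 422 of 13463 tested genes differed between genotypes at an adjusted p of 0.05 in limma, 178 higher and 244 lower in mutants. The groups did not overlap in 421 of these, and in 25.06% of all tested genes, where chance gives 10%. In the deposited values the median gene had a log2 fold change of -0.125, and gene lists are therefore set against that median. Counts of list members that pass in limma test each gene against 0 instead, and so carry that lower median. With median-of-ratios scaling the median was -0.012 and the calls split into 282 higher and 156 lower, and with quantile normalization it was -0.0198 with 264 higher and 163 lower. The share of reads on mitochondrial ribosomal RNA was 28.77%, 26.96% and 30.35% in the control libraries and 32.23%, 38.24% and 32.67% in the mutant libraries. With it left out of the depth the split was 268 higher and 149 lower. The number of genes called was 210 without control replicate 1, 1083 without control replicate 3, 202 without mutant replicate 1, 148 without mutant replicate 2 and 243 without mutant replicate 3.

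**Figure D2:**
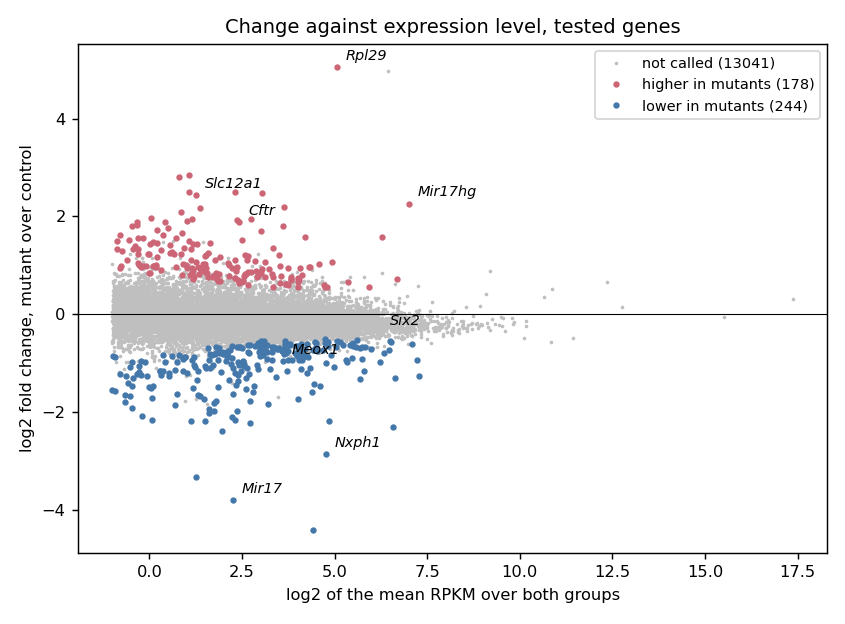
Log2 fold change of mutant over control (vertical axis) against the log2 of mean RPKM (horizontal axis) for the 13463 tested genes, one dot per gene. Genes past adjusted p 0.05 are coloured, 178 higher and 244 lower, and the named genes include Rpl29 at the top and Mir17 near the bottom.

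Several of the largest changes fell on genes that share at least 20% of their 31-base words with another gene. These are uncertain because reads can be counted to either gene. Rpl29, a ribosomal protein gene with 49.08% of its 31-base words present in another gene, was listed at 1.48 ± 0.0885 RPKM in controls and 65.4 ± 4.93 in mutants (SD, n = 3). The pseudogene Gm8210, chosen after its values were seen and with 100% of its words present in another gene, went from 41 ± 6.57 to 1.47 ± 0.273 RPKM (SD, n = 3). By shared words the closest copy of Rpl29 was Gm6344, whose reads were not compared, and an exchange of reads between Rpl29 and Gm8210 was not tested. The other such genes among the largest rises were Tdg (log2 fold change 2.48), Slfn9 (2.19), Gpr137b-ps (2.18), Zfp971 (1.97), Tuba1b (1.94) and Ahcy (1.92). Slfn9 and Gpr137b-ps shared the least, 22.76% and 23.53% of their words. The closest copies did not lose the reads that some of these rising genes gained. Summed over the 3 libraries of each genotype, controls first, Tdg had 634 and 3924 reads and Tdg-ps 16 and 27, Slfn9 had 1498 and 6837 and Slfn10-ps 72 and 54, and Tuba1b had 353 and 1462 while Tuba1c rose too (0.67). Gpr137b-ps had 163 and 1142 reads and Gpr137b 1004 and 730, and Zfp971 had 44 and 694 and Gm14288 93 and 172. Each of these 5 copies was chosen after its values were seen. Among the falls, Hmga1b had a log2 fold change of -2.23, with 1631 reads over the controls and 327 over the mutants, while its copy Hmga1, chosen after its values were seen, had 90 and 307 reads, a smaller gain than that loss. Rpl15-ps6, for which sequence sharing was not computed, had -2.3. With no filter on low values, and with robust variance moderation, Hmga1b (limma adjusted p 0.137 and 0.145) and Rpl15-ps6 (0.102 and 0.126) did not pass. Klk1b22, with 41.09% shared, was listed at 4.25, 3.08 and 6.99 RPKM in the controls and at 0 in each mutant library. Of the called genes that could be checked, 77 of 387 (19.9%) shared at least 20% of their words with another gene, against 865 of 12270 (7.05%) of the genes not called (Fisher's exact test, two-sided p = 6.96e-16). Called genes also crowded on chromosome 14, which holds the targeted locus. There 48 of 470 tested genes (10.2%) were called, against 2.91% on the other autosomes (Fisher's exact test, two-sided p = 6.02e-13).

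**Figure D3:**
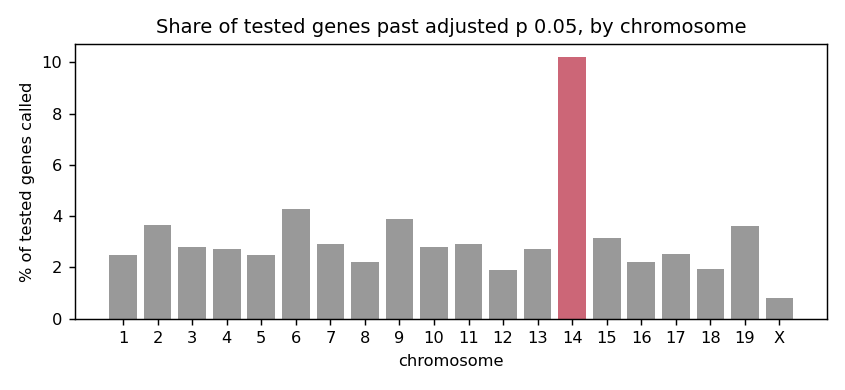
Share of tested genes past adjusted p 0.05 (vertical axis, percent) on each chromosome (horizontal axis). Chromosome 14 stands at 10.2%, and the other autosomes lie between 1.91% and 4.28%.

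Of 27 nephron progenitor genes, 1 rose (Tmem100), 2 fell (Meox1 and Capn6) and 24 did not pass in limma. Meox1, a homeobox gene, fell from 16.2 ± 0.336 to 8.16 ± 0.937 RPKM (SD, n = 3; log2 fold change -0.95, limma adjusted p 0.00271). Capn6 had a log2 fold change of -0.54 and Tmem100 of 0.95. Six2, which keeps progenitors undifferentiated, had a log2 fold change of -0.37 (limma adjusted p 0.249) and Cited1 of -0.39 (0.235), and neither passed. Adjusted over the list alone, 1 gene was higher and 7 were lower, a count against 0 that carries the lower median of all genes. The list median was -0.28 in the deposited values, -0.16 with median-of-ratios scaling and -0.06 with quantile normalization. The list as a whole did not pass camera (adjusted p 0.089; adjusted p = 0.689 with an estimated correlation), and it did pass without control replicate 1 (0.0304) or control replicate 2 (0.0373). The call for Capn6 was lost without control replicate 1 (limma adjusted p 0.116), control replicate 2 (0.0609), mutant replicate 1 (0.154), mutant replicate 2 (0.133) or mutant replicate 3 (0.122) and with median-of-ratios scaling (0.139), and that for Tmem100 without control replicate 1 (0.163), mutant replicate 1 (0.18) or mutant replicate 2 (0.194). With the replicate number as a block neither Capn6 (0.0559) nor Tmem100 (0.0538) passed.

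Genes of committed progenitors and the renal vesicle, the first epithelial stage of the nephron, lay higher in mutants relative to other genes. Of 19 members 16 lay above the median of all genes, and the list median was 0.46 above it (camera adjusted p 4.89e-06; adjusted p = 0.501 with an estimated correlation). Cdh6, a cadherin gene, rose from 5.45 ± 0.292 to 10.5 ± 2.16 RPKM and the homeobox gene Emx2 from 1.2 ± 0.543 to 2.78 ± 0.19 (SD, n = 3), and 17 members did not pass in limma. Wnt4, the inducer of epithelial conversion, had a log2 fold change of 0.37 (limma adjusted p 0.202; 0.0487 with median-of-ratios scaling and 0.048 to 0.381 over the alternatives run). Adjusted over the list alone, 4 genes were higher and 1 was lower. The call for Cdh6 was lost without mutant replicate 1 (limma adjusted p 0.0776) or mutant replicate 3 (0.0576), and that for Emx2 without control replicate 1 (0.134), mutant replicate 1 (0.106), mutant replicate 2 (0.161) or mutant replicate 3 (0.103). The nephron tubule list lay higher too, by 0.7 at its median (camera adjusted p 0.00484, and 0.501 with an estimated correlation). Slc12a1 was called, over all genes and adjusted over the list alone, and the other 4 members were not. Only 5 of its 20 genes were tested, and Slc12a1 and Hnf4a, at 0.326 and 0.374 RPKM in controls, passed the filter through the mutants. Much of the rise of Lrp2 and Fxyd2 came from mutant replicate 3. Lrp2 was at 1.92, 1.88 and 3.76 RPKM in mutant replicates 1 to 3, and Fxyd2 at 1.56, 1.2 and 3.95. The list passed without any 1 library (camera adjusted p 0.000721 to 0.0186). None of 11 podocyte genes passed in limma over all genes or adjusted over the list alone, 2 did at an unadjusted p of 0.05 and 0 with voom, and the list did not pass (camera adjusted p 0.312).

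Markers of other cell types that a sort can carry were also measured. The macrophage and leukocyte list lay highest relative to other genes, with 6 of 6 tested members above the median of all genes and a list median 1.25 above it (camera adjusted p 2.99e-08, and 0.501 with an estimated correlation). Only these 6 of its 14 genes passed the filter. Ctss, Tyrobp and C1qc, at 0.208, 0.433 and 0.481 RPKM in controls, passed it through their mutant values. With mitochondrial ribosomal RNA left out of the depth 10 members were tested. All 10 lay above the median of all genes, the list median was 0.94 above it and 2 were called. Fcer1g, which encodes an Fc receptor chain, rose from 0.73 ± 0.0378 to 2.41 ± 0.118 RPKM and the cathepsin gene Ctss from 0.208 ± 0.148 to 1.57 ± 0.406 (SD, n = 3). Tyrobp rose with a log2 fold change of 1.23, and its call was lost without mutant replicate 1 (limma adjusted p 0.142), mutant replicate 2 (0.236) or mutant replicate 3 (0.129). Adjusted over the list alone, 5 genes were higher. In the interstitium list 16 of 16 members lay above the median of all genes, and the list median was 0.6 above it (camera adjusted p 4.94e-05; adjusted p = 0.501 with an estimated correlation). No interstitium gene passed in limma over all genes or adjusted over the list alone, and 4 did at an unadjusted p of 0.05 and 0 with voom. These counts depended on single controls, since without control replicate 2 the 4 members followed under each alternative, Col1a2 (limma adjusted p 0.0228), Dcn (0.0275), Lum (0.00804) and Col1a1 (0.0271), passed over all genes. The mean log2 level of the list was 3.28, 3.8 and 2.49 in control replicates 1 to 3 and 3.28, 3.82 and 3.76 in mutant replicates 1 to 3, so that most of the rise came from the low value of control replicate 3. The list still passed without that library (camera adjusted p 0.0473). The ureteric bud and collecting duct list lay higher by 0.53 at its median (camera adjusted p 0.0228, and 0.501 with an estimated correlation). Only 7 of its 19 genes were tested. Of these Tfcp2l1 and Cdh1, at 0.405 and 0.282 RPKM in controls, passed the filter through their mutant values. Of the 7 tested members 0 passed in limma over all genes, 1 adjusted over the list alone, 3 at an unadjusted p of 0.05 and 1 with voom. That list did not pass without control replicate 3 (0.0779), mutant replicate 2 (0.208) or mutant replicate 3 (0.115), or with median-of-ratios scaling (0.0725). Endothelium (camera adjusted p 0.615) and erythroid genes (0.0688) did not pass, with 0 of 5 members each called in limma, adjusted over the list alone, at an unadjusted p of 0.05 or with voom; without mutant replicate 3 the erythroid list passed (0.0186). Xist, transcribed from the inactive X of females, was at 154, 0.034 and 0.0278 RPKM in the controls and 60.1, 180 and 122 in the mutants, so that the sex mix of the pools differed. The sex-linked list did not pass (camera adjusted p 0.312), with 0 of 5 members called in limma and 1, Xist, adjusted over the list alone, at an unadjusted p of 0.05 and with voom.

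Transcriptional responses to FGF signalling, which maintains progenitors, lay lower in mutants relative to other genes. Of 13 FGF and MAPK response genes 3 lay above the median of all genes, and the list median was below it (difference -0.29, camera adjusted p 0.00642; adjusted p = 0.501 with an estimated correlation). Etv4 had a log2 fold change of -0.67 (limma adjusted p 0.0567) and Etv5, of which 32.34% of the sequence is shared with another gene, of -0.51 (0.0691). In limma 0 members passed over all genes, 8 were lower adjusted over the list alone and at an unadjusted p of 0.05, and 2 with voom. These counts test against 0 and carry the lower median of all genes. The list median was -0.41 in the deposited values and -0.29 with median-of-ratios scaling, where its difference from all genes was -0.28. The G2 and M phase list lay higher by 0.18 at its median (camera adjusted p 0.00859; adjusted p = 0.501 with an estimated correlation), though not without mutant replicate 1 (0.0695). Of its 24 members 0 passed in limma over all genes or adjusted over the list alone, 4 at an unadjusted p of 0.05 and 1 with voom. Mki67, a marker of cycling cells, had a log2 fold change of 0.61 (limma adjusted p 0.0912; 0.00202 without control replicate 3 and up to 0.281 over the alternatives run). S phase and E2F genes did not pass (camera adjusted p 0.612), nor did apoptosis and p53 genes (0.696), among them the pro-apoptotic Bcl2l11 (log2 fold change -0.27, limma adjusted p 0.271) and the cell cycle inhibitor Cdkn1a (0.27, adjusted p 0.436). In both lists 0 members passed in limma over all genes, adjusted over the list alone or with voom, and 2 did at an unadjusted p of 0.05.

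Mitochondrially encoded genes lay higher by 0.49 at their median (camera adjusted p 0.00399; adjusted p = 0.501 with an estimated correlation), though not without mutant replicate 2 (0.139), the library with the largest share of mitochondrial ribosomal RNA. Of 9 members 0 passed in limma over all genes, 2 were higher adjusted over the list alone, 3 at an unadjusted p of 0.05 and 2 with voom; ND2, a subunit of complex I, had a log2 fold change of 0.88 (limma adjusted p 0.0558). The nuclear genes of oxidative phosphorylation did not pass (camera adjusted p 0.052), and did without control replicate 3 (4.7e-05). Of these 26 genes 0 passed in limma over all genes, adjusted over the list alone or with voom, and 4 at an unadjusted p of 0.05. In dissociation stress (camera adjusted p 0.503) Atf3 rose and Junb fell, with log2 fold changes of 0.99 and -1.16, and 1 gene was higher and 2 lower adjusted over the list alone. The call for Atf3 was lost without control replicate 1 (limma adjusted p 0.0825), control replicate 2 (0.0536), mutant replicate 1 (0.138) or mutant replicate 3 (0.106), and that for Junb without control replicate 1 (0.0809), mutant replicate 1 (0.0689) or mutant replicate 2 (0.114). Wnt and beta-catenin response did not pass (camera adjusted p 0.0526) and did without control replicate 2 (0.0262). TGF-beta and BMP response (0.12) and glycolysis and hypoxia (0.696) did not pass. In these 3 lists 0 members passed in limma over all genes or adjusted over the list alone, 2, 1 and 4 did at an unadjusted p of 0.05 and 0, 1 and 0 with voom. The cystic kidney list did not pass (camera adjusted p 0.203), with Cftr its single called gene of 24, also adjusted over the list alone. The median and the mean of the log2 fold changes differed in sign for the reported target (-0.01 and 0.04), cystic kidney (-0.05 and 0.05), TGF-beta and BMP (-0.02 and 0.07) and sex-linked lists (-0.01 and 0.86), and the sign of the camera statistic was positive for each. It was positive also for endothelium, apoptosis and p53, and glycolysis and hypoxia, none of which passed, while their medians (-0.08, -0.15 and -0.15) and means (-0.02, -0.07 and -0.07) were negative. No list call held with an estimated correlation.

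**Figure D4:**
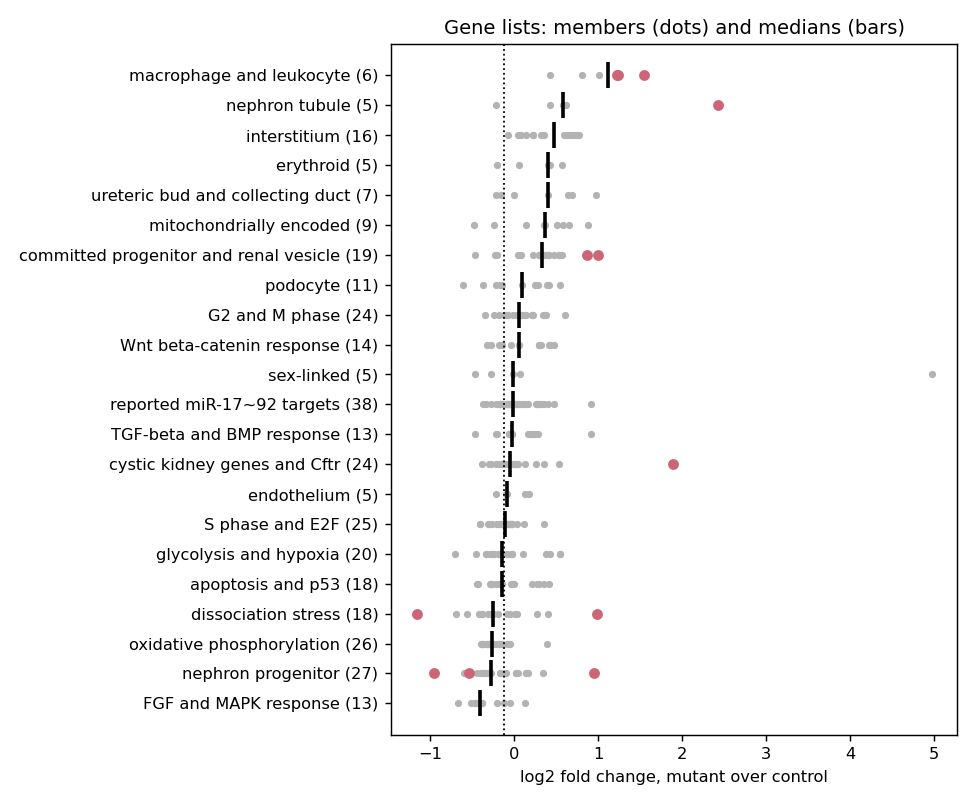
Log2 fold change of mutant over control (horizontal axis) for the members of each gene list (vertical axis, with the number tested); grey dots did not pass, coloured dots passed adjusted p 0.05 in limma, bars are list medians and the dotted line is the median of all genes, -0.125. The macrophage and leukocyte median lies at 1.12 and the FGF and MAPK median at -0.41.

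Genes with sites for the deleted microRNAs lay slightly higher in mutants relative to other genes. Of 11715 tested genes with an annotated 3' UTR, 1720 had an 8mer site for at least 1 of the 4 seed families of the cluster, and their median log2 fold change was 0.0784 above that of genes without one (camera adjusted p 0.0217; adjusted p = 0.7 with an estimated correlation). By family the medians lay above those of other genes by 0.0874 for miR-17 (site GCACTTTA, camera adjusted p 0.0217), 0.0897 for miR-92 (GTGCAATA, 0.0217), 0.0633 for miR-19 (TTTGCACA, 0.0552) and 0.0462 for miR-18 (GCACCTTA, 0.161), and each gave an adjusted p = 0.7 with an estimated correlation. Medians at least as high came from 1 of 296 shuffled 8mers for the miR-17 site, 0 of 448 for miR-92, 9 of 296 for miR-19 and 2 of 236 for miR-18. Among the 1720 genes 27 were called higher and 25 lower. The calls for the 1720 genes and for the miR-17 and miR-92 sites were lost without control replicate 2 (camera adjusted p 0.254) and without mutant replicate 1 (0.0778), and the miR-19 sites passed without control replicate 3 (0.0183), mutant replicate 2 (0.0486) or mutant replicate 3 (0.0332). The miR-19 sites passed also with quantile normalization (0.0236), median-of-ratios scaling (0.0261), a mean RPKM of at least 1 (0.0423), sample weights (0.0326), depth without mitochondrial ribosomal RNA (0.0352) and at least 2 sites of 8mer or 7mer-m8 kind (0.0336). Of 38 tested genes reported elsewhere as targets of the cluster 29 lay above the median of all genes, with a list median 0.12 above it (camera adjusted p 0.0479; adjusted p = 0.639 with an estimated correlation). In limma 0 of them passed over all genes or adjusted over the list alone, 2 did at an unadjusted p of 0.05 and 2 with voom. That list did not pass without control replicate 1 (0.0795), control replicate 3 (0.0753), mutant replicate 1 (0.0725) or mutant replicate 3 (0.078).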

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

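Alternatives added after the data were seen were voom on recovered reads, mitochondrial rRNA left out of the depth, a Y-linked covariate, robust eBayes and the restriction off chromosome 14. Mir17 stayed lower and Mir17hg and Cftr higher, past 0.05, in each refit that held them, and no called value reversed. The numbers of genes changed, higher and lower were 143, 65 and 78 with no filter on low values, 730, 284 and 446 at an adjusted p of 0.1, 690, 295 and 395 with voom, and 264, 118 and 146 with the Y-linked covariate. The looser threshold passes more genes. For the others the cause was not tested. With no filter 23229 genes were tested, and whether that number or the variance model lowered the count was not separated. Median-of-ratios scaling gave 282 higher and 156 lower, and depth without mitochondrial rRNA gave 268 and 149, with a median change of -0.0125. Among the fewer genes off chromosome 14 and without shared sequence 278 were called, 115 of them higher. Leaving out 1 library gave between 148 and 1083 changed genes, 66 to 270 higher and 82 to 813 lower. With the replicate number as a block, 393 genes were called, 168 higher and 225 lower; deviations of same-numbered libraries correlated at 0.05, 0.16 and 0.15, each library correlating best with its own number, which is a hint from the data and not a pairing in the design. Under the block the erythroid list passed (camera adjusted p 0.0473), as did oxidative phosphorylation (0.0497), and it changed no other list call. Among named genes the block ended the calls for Capn6 (limma adjusted p 0.0559) and Tmem100 (0.0538), and Lyz2 passed (0.0232).

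Each list call was lost with an estimated correlation, at adjusted p 0.501, or 0.639 for reported targets, and the seed site call at 0.7. With no filter, reported targets (0.324), G2 and M phase (0.0717), mitochondrially encoded (0.0717) and seed sites (0.499) lost their calls, while nephron progenitor (0.00691) and oxidative phosphorylation (0.00207) gained one. The ureteric bud and collecting duct call was lost at a mean RPKM of at least 1 (0.11), with quantile normalization (0.127), median-of-ratios scaling (0.0725), sample weights (0.0744) and depth without mitochondrial rRNA (0.0673). That of reported targets was lost without a trend (0.0555) and with voom (0.0555). Wnt and beta-catenin response passed with a pseudocount of 0.1 (0.05) and the Y-linked covariate (0.0458), oxidative phosphorylation with the same settings (0.05 and 0.0458) and with sample weights (0.0223), and erythroid with sample weights (0.0476). Seed sites counted as 8mer or 7mer-m8 gave 0.181. The cause was not tested.

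Leaving out 1 library moved some lists across the threshold, with camera adjusted p of 0.00312 to 0.0695 for G2 and M phase, 0.0262 to 0.136 for Wnt beta-catenin response, 0.0186 to 0.172 for erythroid, 0.000169 to 0.139 for mitochondrially encoded, 0.0304 to 0.405 for nephron progenitor, 4.7e-05 to 0.613 for oxidative phosphorylation, 0.0327 to 0.0795 for reported miR-17~92 targets, 0.000721 to 0.208 for ureteric bud and collecting duct, and 0.00545 to 0.254 for seed sites. Among the 109 named genes beside Mir17 and Mir17hg, over 19 refits, 46 results passed only in the alternative, 60 only as reported and 1946 kept their side of the threshold. Depth limits the microRNA entries, of which Mir17 had at most 31 reads in a library and the others fewer.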

Other observations

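The tests of the crowding on chromosome 14, of the neighbours of Mir17hg, of Mir17hg against scaling (in part on scalings that had been planned) and of the differences between cell type scores were chosen only after the result was seen.

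Within the mitochondrially encoded list, ND2 had a log2 fold change of 0.88 (limma adjusted p 0.0558) and ND1 of -0.48 (0.269), and neither passed. Of the 12 tested genes within 5 Mb of Mir17hg, 2 of them within 1 Mb, the glypican gene Gpc5, which begins downstream of it, was the single one called (log2 fold change 0.95, limma adjusted p 0.0401). Rpl15, a ribosomal protein gene on chromosome 14 with 30.92% of its sequence shared with another gene, went from 141 ± 13.3 to 56.9 ± 8.93 RPKM (SD, n = 3). Gpc5 and Rpl15 were chosen after their values were seen.

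The genotypes gave 422 called genes, and the highest count over the other 9 splits of the 6 libraries was 0 in limma (1 of 10 splits as large). At an unadjusted p of 0.05 the genotypes gave 2641 genes and the other splits 143 to 1271. The 10 splits are too few for a share under 0.05.

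Called genes crowded on chromosome 14 (10.2% of tested genes, against at most 4.28% on another autosome), which is what a strain haplotype carried along with the targeted allele would give, and this stays a candidate explanation. Reads shared between copies as the whole cause are argued against for genes with under 20% of their words in another gene. That limit was set after results had been seen, and genes below it can still share some words. Among them 7.66% were still called there, against at most 4.43% on another autosome (Fisher's exact test, two-sided p = 1.09e-07). An unequal sex mix as the whole cause is argued against. With the level of Y-linked genes as a covariate 264 genes were called in limma, 6.6% of those tested on chromosome 14 and at most 2.85% on another autosome. With the RPKM of Xist as a covariate 159 were called, 4.89% there and at most 1.58% on another autosome (Fisher's exact test, two-sided p = 2.33e-09 and 3.63e-09). An effect of the deleted cluster on genes of its own chromosome stays open and was not tested.

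Mir17hg rose while reads counted to the microRNA entries fell, and mature microRNAs were not measured. Scaling is argued against, since its lowest log2 fold change over 4 other scalings was 2.28. A rise of the whole neighbourhood is argued against, since the 12 tested genes within 5 Mb had a median log2 fold change of 0.305 (SD 0.36). A change in the stability or processing of the remaining transcript after the deletion, or a strain difference in the entry itself, may explain the rise, and neither was tested.

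Macrophage markers sat higher in mutants relative to other genes. So did interstitium markers, but their mean log2 level in mutants (3.28, 3.82 and 3.76) was close to that of control replicates 1 and 2 (3.28 and 3.8) and above that of control replicate 3 (2.49). Most of the interstitium rise thus came from that control, though the list still passed without it (camera adjusted p 0.0473). The endothelium score changed by less than the macrophage score. The difference was -1.06 (95% interval adjusted for 6 pairs of lists -1.57 to -0.554), and -1.04 among members under 5 RPKM in controls, which keeps all 6 macrophage genes. Of these Ctss, Tyrobp and C1qc, at 0.208, 0.433 and 0.481 RPKM in controls, passed the filter through their mutant values. That selection favours a macrophage rise, so the difference does not decide whether the scores of all other cell types rose alike. A larger share of outside cells need not raise all scores alike, so the difference does not decide on that share. The endothelium score rests on 5 genes, with Ramp2 at 71.5 RPKM in controls. A single mutant library is argued against for macrophage genes, whose list median stayed at least 1.21 above that of all genes without any 1 of them. More macrophages in the mutant pools, which a sort for the reporter would be set to exclude, or expression of these genes by the progenitors themselves may explain the pattern, and genotype and composition were not separated in these pools. The mutant means of Lyz2 and Fcer1g were 2.99 and 2.41 RPKM.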
